A study of Mus musculus with 38 samples.

How the data were processed

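The data are RNA-seq counts from mice that received MPTP, a toxin of dopaminergic neurons, or saline by injection 1 time a day for 3 days, with the brain taken 6 hours after the last injection. Ribosome-bound RNA was captured by translating ribosome affinity purification (TRAP) from dopaminergic neurons, astrocytes or microglia. The substantia nigra was sampled for all 3 cell types and the striatum for astrocytes and microglia. The 38 libraries make up 10 groups of a cell type, region and treatment (34 libraries) and 4 single libraries whose cell type label is All, called unselected here. The labels do not state that the libraries come from separate animals, so the p-values measure the spread between samples.

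The deposited files hold raw counts per gene, 1 library per file, with no normalization. The submitters' notes name featureCounts 1.5.0-p3 and the mouse build mm10; the aligner, the annotation and the strand setting are not given in the sources used here. The files of neurons and microglia list 54532 genes and those of astrocytes and unselected tissue list 56243, so the 54439 gene identifiers shared by all were used, which hold at least 99.833% of the counts of each library. Gene coordinates are those of mm10. Total counts ran from 16834724 to 25735536 per library.

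Each cell type was fitted on its own over all of its groups with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, a quasi-likelihood fit and F tests, two-sided, with Benjamini-Hochberg (BH) adjustment over all genes tested and a threshold of 0.05. The comparisons were MPTP against saline in each cell type and region, the difference of that effect between regions, and substantia nigra against striatum in saline. A second fit over the 6 groups of the substantia nigra gave an F test of whether the MPTP effect differed among the 3 cell types. It also gave the genes enriched in each cell type in saline, with a log2 fold change above 1 and an adjusted p under 0.05 against both others. Levels are TMM-scaled CPM, except values of single libraries and Xist, which use plain library sizes, with the standard deviation (SD) between libraries, and fold changes are log2 values with their standard error (SE).

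Lists of cell type markers, glial states, immune signalling, stress responses, metabolism and other processes, 44 in all, were tested with limma 3.58.1 camera at a preset correlation of 0.01 on log2 CPM with a prior count of 3, BH-adjusted over the lists of a comparison. A list needed 3 measured members. Of 166 list calls over 9 comparisons, 4 held when the correlation between genes was estimated from the data. These are the integrated stress response list in neurons and the interferon, cytokine and proliferation lists in microglia of the substantia nigra. Each list described below therefore carries its adjusted p with an estimated correlation.

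The groups, comparisons, tests, lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule takes, per treatment or region comparison, the 6 highest and 6 lowest log2 fold changes among protein-coding genes past the threshold, with a mean log2 CPM of at least 1 and no overlap between the libraries of the compared groups. It adds the key genes of the cell type and the 3 members with the smallest p of every list past 0.05. That last part was narrowed to the 5 lists with the smallest camera p after the list results had been seen. For interactions the rule takes the 5 genes with the smallest p, and for enriched genes the 5 highest plus the marker list. Some genes that the rule takes are not reported here. The 6 genes plotted per library were chosen after their values were seen.

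A gene at 0 in a whole group is given as a lower bound against 3 counts over the group, and with 1 to 3 counts as a ratio with its 95% counting interval. Intervals and bounds cover counting error only. Alternatives fixed in advance were other scaling (RLE size factors, plain library sizes), other filters (none, a mean of at least 50 counts), DESeq2 1.42.0, limma voom with quality weights, a threshold of 1 on the absolute log2 fold change, a block for equal replicate numbers, an oligodendrocyte marker covariate, other sets of libraries in the fit, fry and an estimated correlation for the lists, and leaving out each library. The oligodendrocyte list is not given under its own covariate, which fixes that outcome. The mean level of its markers did not overlap between the groups compared in neurons, striatal astrocytes, striatal microglia or the regions of saline glia. There the covariate can take up the compared difference itself. Calls lost or turned under it there cannot tell RNA of other cells from an effect.

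Alternatives added after seeing the data use a library length score, the mean log2 CPM of protein-coding genes with over 8000 nucleotides of exon minus that of genes under 1500. Members of the tested lists were not left out of this score. These alternatives also use Xist, as a covariate or by leaving out saline libraries with more than 1 CPM of it. For the list calls of treatment comparisons they leave out each library in turn. For neurons they add the 2 clusters of the length score, alone and as a batch term. For neurons and astrocytes of the striatum they add a block by the numbers in the files' own headers, which differ from the labels in 1 library each. Replicate numbers were taken to pair samples where every same-numbered pair of libraries had r across genes of at least 0.1. That held in all treatment and region comparisons but astrocytes of the substantia nigra and regions of saline microglia. In the striatum most MPTP libraries correlated best with another number, so pairing is uncertain there.

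Other splits of the samples were counted by refitting, with at most 100 drawn per comparison and 90 for the enriched genes. The number of draws for the cell type test and the enriched genes, and the definition of a split for the enriched genes, were changed after first counts had been seen. The fits were tested on simulated data with known changes. For treatment and region comparisons 55% to 78% of the genes changed by 1 log2 unit and 95% to 98% of those changed by 2 were recovered. For the interactions and the cell type test those shares were 28% to 32% and 87% to 88%. The highest share of false calls was 7.4%. In the simulated data the changed list was called in all 9 comparisons and no unchanged list was. Genes and libraries were drawn independently there, without same-numbered pairs or clusters of length score. The simulation therefore does not test the list calls under correlation between genes.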

Results

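The series profiled ribosome-bound RNA of dopaminergic neurons, astrocytes and microglia from mice given MPTP or saline, to find responses that depend on cell type and region. Dopaminergic neurons of the substantia nigra had 4 saline and 5 MPTP libraries. Astrocytes had 3 and 3 in the substantia nigra and 3 and 3 in the striatum. Microglia had 3 and 3 in the substantia nigra, and 4 saline and 3 MPTP libraries in the striatum. Unselected RNA had 1 library per region and treatment and so no replicate check. Total counts per library ran from 17410501 to 20051933 for neurons, 18843534 to 21665150 for astrocytes of the substantia nigra and 20325313 to 25735536 for those of the striatum. They ran from 18313304 to 19663884 for microglia of the substantia nigra, 16834724 to 20971364 for those of the striatum and 17778441 to 20172397 for the unselected libraries. Xist, the X-inactivation RNA of female cells, exceeded 1 CPM in 9 of 19 saline libraries and in none of the 19 MPTP libraries. Genes given as the highest or lowest of a treatment or region comparison had no overlap between the libraries of the compared groups.

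The first comparison asks how specific the captured RNA was to each cell type in the saline substantia nigra. Th, the enzyme that makes the dopamine precursor, lay at 4571 ± 454 CPM (SD, n = 4) in neurons, 15.4 ± 6.05 (n = 3) in astrocytes and 180 ± 23.1 (n = 3) in microglia. Ndrg2, an astrocyte gene, lay at 13630 ± 57.5 CPM in astrocytes against 161 ± 11.2 in neurons and 121 ± 11.7 in microglia. C1qb, a complement subunit made by microglia, lay at 2574 ± 427 CPM in microglia against 2.69 ± 0.67 and 3.05 ± 1.495 in neurons and astrocytes. Of 18021 genes, 1405 were enriched in neurons, 2607 in astrocytes and 1972 in microglia (edgeR, BH). The enriched genes held 20 of 21 dopaminergic markers, all 20 astrocyte markers and all 22 microglial markers. The exception was Aldh1a1, a retinaldehyde dehydrogenase, at 3852 ± 503 CPM in neurons and 2264 ± 416 in astrocytes. Pan-neuronal markers had a mean log2 CPM of 8.06 ± 0.10 in the microglial libraries, 8.18 in 1 unselected library and 7.12 ± 0.17 in neurons, and blood cell markers 5.81 ± 0.65 in astrocytes and 2.70 in the unselected library.

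By the smaller of their log2 fold changes over the other cell types, the highest genes in neurons were Slc10a4 (5.38), Tyrp1 (5.12), Anxa1 (5.04), Npbwr1 (4.97) and Chrna6 (4.82), a nicotinic receptor subunit. In astrocytes they were Hgs, Wdr74, Kcne1l (7.85), Sfrp5 (7.26) and Agt (7.22), which encodes angiotensinogen. Hgs had no counts in neurons or microglia, and was at least 1330-fold and at least 985-fold higher in astrocytes. Wdr74, at 0 in both, was at least 282-fold and at least 208-fold higher. The files of neurons and microglia hold no counts of Hgs in any of their 22 libraries, so its value may rest on how the files were made as well as on cells, which was not tested. In microglia the highest were Slamf6, Ccl24, Ltc4s, Bcl2a1b and H2-Ob. Over neurons and astrocytes, Slamf6 was at least 257-fold and 201-fold, Ccl24 at least 253-fold and 198-fold, and Bcl2a1b at least 191-fold and 150-fold higher. Ltc4s, a leukotriene synthase, had ratios of 1500 (95% interval 415 to 12400) over neurons and 2350 (422 to 93000) over astrocytes. H2-Ob was at least 661-fold higher than in neurons, with a ratio of 1550 (278 to 61400) over astrocytes.

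**Figure D1:**
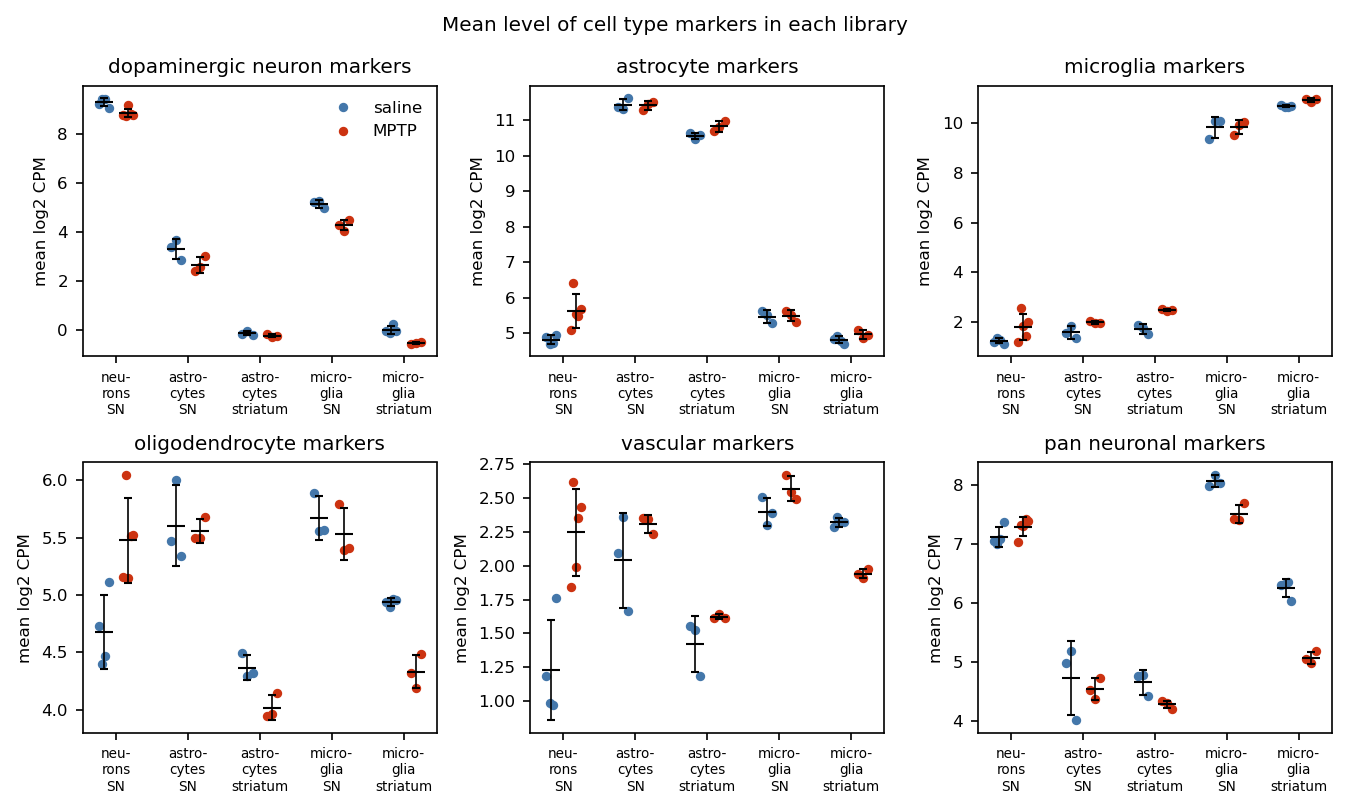
Mean log2 CPM of 6 marker lists (y axis) in each library (points), by cell type and region (x axis) and treatment (colour), with the group mean and SD as bars. Each captured cell type carries its own markers highest, dopaminergic markers lie at 5.14 in saline microglia of the substantia nigra against 0.03 in those of the striatum, and the glial and vascular lists are higher in MPTP than in saline libraries of neurons.

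In dopaminergic neurons, immediate early and integrated stress response genes were higher after MPTP. Atf3, a transcription factor of the stress and axon injury response (chromosome 1, 191170296 to 191218039, mm10), rose from 0.13 ± 0.13 CPM (SD, n = 4) to 11.1 ± 4.499 (n = 5), a log2 fold change of 6.33 ± 0.55 (SE; edgeR, BH-adjusted p = 0.00322). By plain library size it was also higher in astrocytes of the substantia nigra (0.33 to 0.53 CPM in saline, 7.21 to 7.97 after MPTP). In microglia there it lay at 6.07 to 9.60 CPM in saline and 30.1 to 54.9 after MPTP. In the striatum the ranges overlapped, for astrocytes (0.32 to 0.78 and 0.19 to 7.75) and microglia (9.88 to 11.8 and 7.22 to 12.1). Among immediate early genes, Egr1 rose by 2.94 ± 0.52, Fos by 2.46 ± 0.32 and the MAP kinase phosphatase Dusp1 by 1.85 ± 0.19 on the log2 scale. Of 13 measured immediate early genes 6 rose (12 adjusted over the list alone), with a median of 1.34 (camera, BH-adjusted p = 3.71e-11, and adjusted p = 0.218 with an estimated correlation). The integrated stress response list had 10 of 21 members higher (12 adjusted over the list alone), among them Chac1 (1.02 ± 0.16), which degrades glutathione, and Cebpb (1.11 ± 0.18). Its median was 0.50 (camera, BH-adjusted p = 3.58e-07, and adjusted p = 0.022 with an estimated correlation). Of 10 axon injury genes 3 rose (6 adjusted over the list alone, median 0.87, camera BH-adjusted p = 0.00018, and adjusted p = 0.0725 with an estimated correlation), and of 15 glucocorticoid response genes 1 (4 adjusted over the list alone, median 0.61, camera BH-adjusted p = 0.000936, and adjusted p = 0.348 with an estimated correlation). No heat shock gene passed (0 of 14, 1 higher and 2 lower adjusted over the list alone, median -0.28, camera BH-adjusted p = 0.013, 0.062 without MPTP library 2, and adjusted p = 0.45 with an estimated correlation). No gene of the unfolded protein response passed (0 of 15, 0 adjusted over the list alone, median -0.225, camera BH-adjusted p = 0.00337, and adjusted p = 0.348 with an estimated correlation). Of 12 Nrf2 genes 1 rose and 1 fell (2 and 2 adjusted over the list alone, median -0.27, camera BH-adjusted p = 0.327, and adjusted p = 0.659 with an estimated correlation).

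The lowest genes in neurons were the growth factor Fgf20 (-1.83 ± 0.24), Pdgfc (-1.46 ± 0.17), the neuronal RNA-binding proteins Elavl2 (-1.40 ± 0.20) and Elavl4 (-1.39 ± 0.19), the transcription factor Etv5 (-1.38 ± 0.14) and the pantothenate kinase Pank3 (-1.38 ± 0.19). Th did not pass, at -0.37 ± 0.13 (edgeR, BH-adjusted p = 0.139), nor did Slc6a3 (-0.49 ± 0.17), the dopamine transporter, Slc18a2 (-0.44 ± 0.15), the vesicular transporter, Ddc (-0.50 ± 0.16) or Cdkn1a (0.31 ± 0.24). With the replicate block Slc6a3 (-0.45, edgeR, BH-adjusted p = 0.0328), Slc18a2 (-0.37, 0.0415), Ddc (-0.47, 0.028) and Cdkn1a (0.36, 0.049) passed and Th (-0.35, 0.061) did not, while Th passed with the block by header numbers (0.0331) and DESeq2 (0.0422). With limma voom the 4 dopamine genes passed and Cdkn1a turned to -0.12. Of 21 dopaminergic markers 2 fell (11 adjusted over the list alone), with a median of -0.37 (camera, BH-adjusted p = 3.82e-07, and adjusted p = 0.346 with an estimated correlation). Their mean log2 CPM was 9.06 to 9.41 in saline libraries, 8.73 to 8.79 in 4 MPTP libraries and 9.15 in MPTP library 3, without which the median was -0.45 (-0.447). In edgeR none of them passed without MPTP library 4 or saline library 1, 2 or 3, 1 passed without MPTP library 5 and 4 without saline library 4.

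Markers of other cells were also higher in the MPTP libraries of neurons. Of 20 astrocyte markers 5 rose (15 adjusted over the list alone), with a median of 0.94, among them Gfap (2.30 ± 0.40), an intermediate filament, Sox9 (1.89 ± 0.28) and Aldh1l1 (1.45 ± 0.30). Of 14 oligodendrocyte markers 2 rose (11 adjusted over the list alone), with a median of 0.90: Cldn11 (1.47 ± 0.28) and Mal (1.32 ± 0.28), while Mbp lay at 1.04 ± 0.25 (edgeR, BH-adjusted p = 0.0575). Of 14 vascular markers 2 rose (11 adjusted over the list alone), with a median of 1.18: the tight junction gene Cldn5 (1.61 ± 0.24) and Pecam1 (1.61 ± 0.31), while Pdgfrb lay at 1.42 ± 0.35 (edgeR, BH-adjusted p = 0.0612). Gfap did not pass with the oligodendrocyte covariate (0.95), in the cluster of high length score (edgeR, BH-adjusted p = 0.079), or without saline library 1, 2 or 3 or MPTP library 4 or 5 (0.056 to 0.0966). With the replicate block Mbp and Pdgfrb passed (edgeR, BH-adjusted p = 0.00386 and 0.00289). With an estimated correlation the adjusted p of these 3 lists was 0.346, 0.348 and 0.338. A tumour necrosis factor receptor gene, Tnfrsf1a (2.53 ± 0.44), and the protease inhibitor A2m (2.19 ± 0.45) were also among the highest.

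In all, 322 of 15554 genes passed in neurons, 130 higher and 192 lower (edgeR, BH). Same-numbered libraries were correlated (r across genes 0.693 to 0.856, and genes are not independent replicates), and 3424 genes passed with the replicate block. The other settings gave 1 (oligodendrocyte covariate) to 9896 (limma voom). Leaving out 1 library gave 27 to 918, so the count depends on single libraries, but 319 calls had no overlap between treatments. The 9 libraries fell into a cluster of low and a cluster of high length score, within which 941 and 103 genes passed.

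In astrocytes of the substantia nigra, cytokine, interferon and reactive astrocyte genes were higher after MPTP. Ccl2, a monocyte chemokine, lay at 0.03 ± 0.03 CPM (SD, n = 3) in saline, 2 counts in all, and at 59.1 ± 17.1 (n = 3) after MPTP, a ratio of 1740 (95% interval 482 to 14400). The transglutaminase Tgm1 (chromosome 14, 55700009 to 55713926) rose by 9.05 ± 0.48 on the log2 scale (SE; edgeR, BH-adjusted p = 1.29e-07), the antiviral GTPase Mx1 by 7.98 ± 0.79, the lipocalin Lcn2 by 7.70 ± 0.91, the chemokine Cxcl10 by 7.45 ± 0.77 and the protease inhibitor Timp1 by 7.28 ± 0.43. All 21 interferon response genes rose (21 adjusted over the list alone), with a median of 4.07, among them Rsad2 (4.92 ± 0.32), Gbp3 (4.82 ± 0.35) and Ifit3 (3.40 ± 0.26). The camera BH-adjusted p was 5.72e-27, and adjusted p = 0.0901 with an estimated correlation. Of 8 cytokine and NF-kB genes 6 rose (6 adjusted over the list alone, median 4.504, camera BH-adjusted p = 1.24e-06, and adjusted p = 0.128 with an estimated correlation). In the same libraries 2 of 22 microglial markers rose, Olfml3 (1.84 ± 0.23) and C1qb (1.03 ± 0.32) (5 adjusted over the list alone, median 0.37, adjusted p = 0.486 with an estimated correlation; without saline library 3 the camera BH-adjusted p was 0.0986). Of 20 dopaminergic markers 6 fell (7 adjusted over the list alone, median -0.65, adjusted p = 0.466 with an estimated correlation).

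Of 13 genes of a list shared by reactive astrocytes 12 rose (12 adjusted over the list alone), with a median of 4.64, among them the sphingosine phosphate receptor S1pr3 (5.66 ± 0.33) and the oncostatin M receptor Osmr (4.74 ± 0.32). All 12 genes of the A2 reactive list rose (12 adjusted over the list alone), with a median of 4.07, among them Emp1 (4.09 ± 0.29) and Cd109 (2.40 ± 0.17). With an estimated correlation, adjusted p = 0.075 for both. Of 14 immediate early genes 8 rose (11 adjusted over the list alone), with a median of 1.497 and adjusted p = 0.0901 with an estimated correlation: Egr1 (5.39 ± 0.42), Junb (4.56 ± 0.35) and Fos (3.63 ± 0.29) are examples. Cytosolic ribosomal protein genes rose in 62 of 74 cases (70 adjusted over the list alone), with a median of 0.85, for example Rps4x (1.67 ± 0.18), Rpl32 (1.28 ± 0.15) and Rpl13 (1.18 ± 0.14). Their camera BH-adjusted p was 2.04e-29, and adjusted p = 0.117 with an estimated correlation. The length score of these libraries, which falls when short transcripts take more of the counts, was 0.43 ± 0.17 (SD, n = 3) in saline and 0.10 ± 0.08 (n = 3) after MPTP.

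Of the key astrocyte genes, Gfap rose by 1.84 ± 0.18, Vim by 1.91 ± 0.26 and the serpin Serpina3n by 2.35 ± 0.23. The water channel Aqp4 (0.09 ± 0.17) and the glutamate transporters Slc1a2 (-0.30 ± 0.14) and Slc1a3 (-0.24 ± 0.12) did not pass, though Slc1a2 did with the Xist covariate (edgeR, BH-adjusted p = 0.0311). The lowest genes were the heat shock gene Hspa1b (-1.90 ± 0.42), the linker histone Hist1h1e (-1.77 ± 0.56), the organic anion transporter Slc22a6 (-1.75 ± 0.29), Ky (-1.64 ± 0.26), Zbtb40 (-1.63 ± 0.33) and Gpr182 (-1.59 ± 0.26). In all, 2326 of 16661 genes passed, 1508 higher and 818 lower (edgeR, BH). Without the 2 saline libraries that hold Xist 1114 passed, with the length score as a covariate 1268, and without MPTP library 1 1217.

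In astrocytes of the striatum, the filament genes Gfap and Vim were among the genes that rose. Gfap (chromosome 11, 102887336 to 102900912) rose from 748 ± 138 CPM (SD, n = 3) to 19650 ± 1914 (n = 3), a log2 fold change of 4.72 ± 0.20 (SE; edgeR, BH-adjusted p = 5.66e-09), and Vim by 4.06 ± 0.28. Tgm1 rose by 8.998 ± 0.46, Timp1 by 7.88 ± 0.44, the sphingosine kinase Sphk1 by 7.46 ± 0.65, the small heat shock protein gene Hspb1 by 7.05 ± 0.65 and Cdsn by 6.97 ± 0.41. Serpina3n rose by 2.41 ± 0.23, Lcn2 by 4.91 ± 0.83 and Aqp4 by 0.78 ± 0.17, while Slc1a2 fell by 0.59 (SE 0.14) and Slc1a3 did not pass at -0.29 ± 0.12. Slc1a3 passed with plain library sizes, voom and the Xist covariate (BH-adjusted p = 0.0369, 0.0167 and 0.037). Lcn2 and Aqp4 did not pass with the oligodendrocyte covariate (edgeR, BH-adjusted p = 0.127 and 0.103), nor Aqp4 without Xist libraries (0.157), nor Slc1a2 with the length covariate (0.0729) or without MPTP library 1 or 2 (0.0638 and 0.054).

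The list shared by reactive astrocytes had 11 of 13 members higher (11 adjusted over the list alone, median 4.19), with S1pr3 at 5.33 ± 0.32, and the A2 list 11 of 12 (11 adjusted over the list alone, median 3.43), with the calcium-binding gene S100a10 at 4.17 ± 0.23 and Cd109 at 2.48 ± 0.17. For both, adjusted p = 0.0734 with an estimated correlation. Of 17 disease-associated microglia genes 8 rose and 1 fell (9 and 1 adjusted over the list alone, median 0.67, adjusted p = 0.0734 with an estimated correlation), among them Spp1 (4.81 ± 0.48), Cd9 (1.87 ± 0.16) and the cathepsin Ctsb (1.29 ± 0.10). Of 22 microglial markers 7 also rose (8 adjusted over the list alone, median 0.61, adjusted p = 0.168 with an estimated correlation). Of 21 interferon genes 15 rose (17 adjusted over the list alone, median 1.45, adjusted p = 0.282 with an estimated correlation), such as Gbp3 (2.602 ± 0.32), Xaf1 (2.44 ± 0.35) and Ifit1 (2.37 ± 0.39). MPTP library 3 held less of some of these genes, with Rsad2 at 2.44 CPM (by plain library size) against 5.52 and 5.34 in the other 2 and up to 2.78 in saline, and without it 16 rose, with a median of 1.84. With MPTP library 1, MPTP library 2 or saline library 2 left out 8, 8 and 7 rose, with medians of 1.32, 1.10 and 1.475. Ribosomal protein genes rose in 62 of 74 cases (69 adjusted over the list alone, median 0.79, adjusted p = 0.168 with an estimated correlation), among them Rps4x (1.79 ± 0.18), Rps12 (1.245 ± 0.16) and Rpl32 (1.18 ± 0.15). Markers of choroid plexus and ependyma (1 of 6 fell, 4 adjusted over the list alone, median -0.765), oligodendrocytes (3 of 14, 3 adjusted over the list alone, median -0.46) and medium spiny neurons (3 of 13, 4 adjusted over the list alone, median -0.45) were lower. For these, adjusted p = 0.168, adjusted p = 0.599 and adjusted p = 0.559 with an estimated correlation (camera, BH). At the preset correlation the camera BH-adjusted p of the medium spiny list was 0.113 without MPTP library 3 and 0.112 without saline library 1, and that of the oligodendrocyte list 0.0582 without saline library 1. The length score was 0.58 ± 0.31 (SD, n = 3) in saline and 0.29 ± 0.14 (n = 3) after MPTP.

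The lowest genes were Rpe65 (-2.79 ± 0.38), the retinoid isomerase, the prokineticin receptor Prokr2 (-2.70 ± 0.64), the histones Hist1h1e (-2.32 ± 0.57) and Hist1h2be (-2.24 ± 0.37), the lipid transporter Abca8a (-2.20 ± 0.32) and Nrep (-2.13 ± 0.25). In all, 2977 of 16661 genes passed, 1679 higher and 1298 lower (edgeR, BH), and 3218 with the replicate block. Without the 2 saline libraries that hold Xist 877 passed, and 885 with the oligodendrocyte marker covariate.

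The region by treatment test asks whether the MPTP effect in astrocytes differed between regions. Positive values mean a larger effect in the substantia nigra. Interferon and immediate early genes had larger effects there, and Gfap a smaller one. Synpo, which encodes an actin-associated protein (chromosome 18, 60593973 to 60660142), differed by 2.68 ± 0.22 (SE; edgeR, BH-adjusted p = 0.00012), the nucleotide kinase Cmpk2 by 4.08 ± 0.38, the receptor of glial cell line-derived neurotrophic factor Gfra1 by 2.75 ± 0.25, Gfap by -2.88 ± 0.25 and A2m by -2.18 ± 0.19. Of 21 interferon genes 11 had a larger effect in the substantia nigra (19 adjusted over the list alone, median 2.12, adjusted p = 0.224 with an estimated correlation). Of 14 immediate early genes 6 did (10 adjusted over the list alone, median 1.82, adjusted p = 0.136 with an estimated correlation). In all, 202 genes passed, 125 positive and 77 negative (edgeR, BH). Without the saline libraries that hold Xist 13 passed, with the oligodendrocyte covariate 102, and 96 without MPTP library 1 of the substantia nigra.

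**Figure D2:**
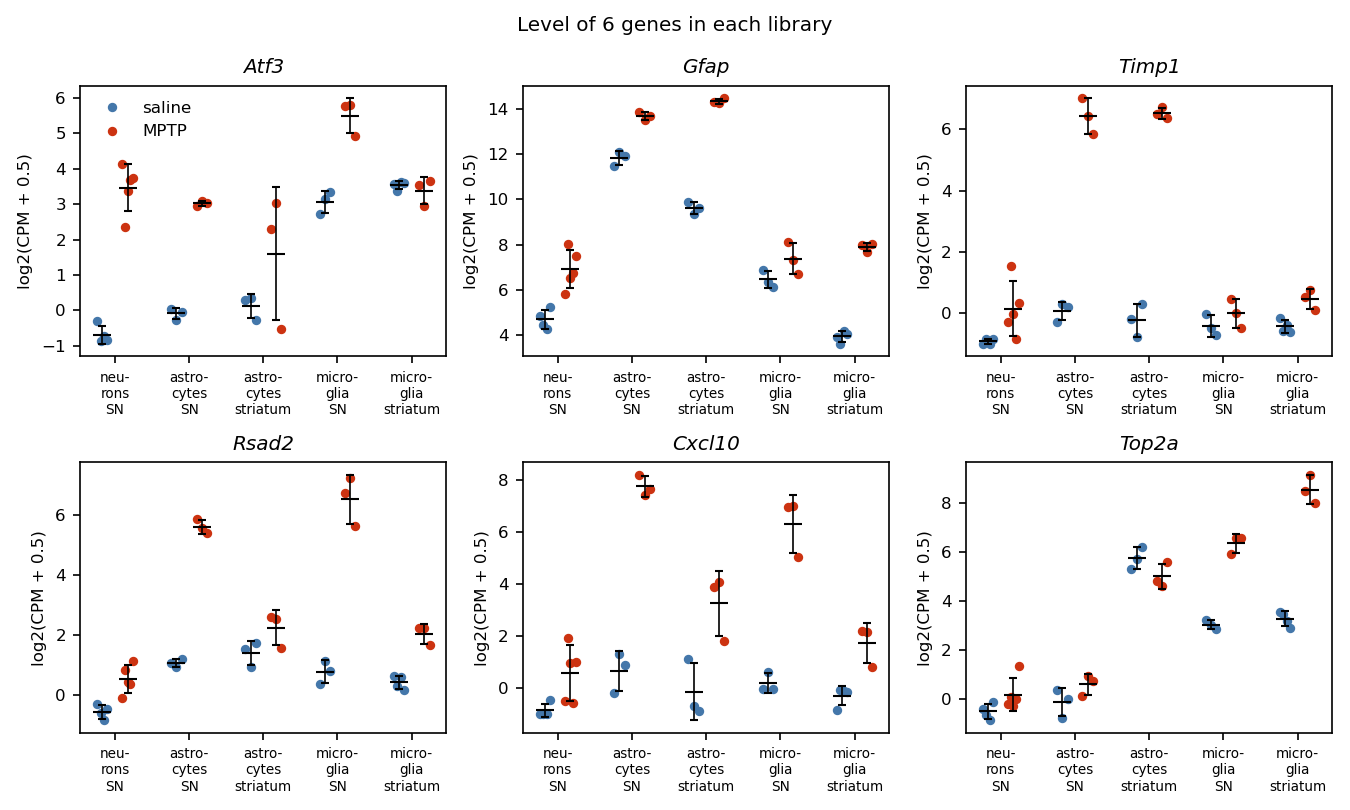
Level of 6 genes in each library (points) as log2(CPM + 0.5), by plain library size, on the y axis, by cell type and region on the x axis and by treatment (colour), with group mean and SD as bars. After MPTP Atf3 was higher in neurons and in astrocytes and microglia of the substantia nigra. Gfap was higher in all 5 comparisons and Top2a in microglia of both regions.

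In microglia of the substantia nigra, interferon, cytokine and cell division genes were higher after MPTP. Cxcl10 (chromosome 5, 92346638 to 92348889) rose from 0.64 ± 0.35 CPM (SD, n = 3) to 85.0 ± 47.8 (n = 3), a log2 fold change of 7.05 ± 0.60 (SE; edgeR, BH-adjusted p = 4.88e-06). The cholesterol hydroxylase Ch25h rose by 6.78 ± 0.46, the interleukin 1 receptor antagonist Il1rn by 6.54 ± 0.74, Rsad2 by 6.26 ± 0.42, the metalloprotease Mmp12 by 6.24 ± 0.61 and the chemokine Ccl3 by 5.62 ± 0.38. Of 21 interferon genes 20 rose (21 adjusted over the list alone, median 2.83), with Isg15 at 4.33 ± 0.30 and Oasl2 at 3.09 ± 0.23. Of 16 cytokine and NF-kB genes 14 rose (15 adjusted over the list alone, median 2.88), with Ccl4 at 5.48 ± 0.40 and Ccl2 at 5.30 ± 0.43. All 20 proliferation genes rose (20 adjusted over the list alone, median 2.75): the topoisomerase Top2a by 3.35 ± 0.30, the cyclin Ccna2 by 3.28 ± 0.31 and the mitotic kinase Bub1 by 3.45 ± 0.35. For these 3 lists, adjusted p = 0.0455 with an estimated correlation.

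Of 20 disease-associated microglia genes 12 rose (14 adjusted over the list alone, median 1.10, adjusted p = 0.0666 with an estimated correlation), among them Cst7 (3.59 ± 0.16), the lipoprotein lipase Lpl (3.98 ± 0.39) and the receptor kinase Axl (1.99 ± 0.22). Il1b (3.14 ± 0.42), Tnf (3.82 ± 0.51) and Cd68 (1.248 ± 0.19), a lysosomal protein of phagocytes, rose. The homeostatic genes P2ry12 (-0.71 ± 0.32), Tmem119 (-0.45 ± 0.18) and Cx3cr1 (-0.20 ± 0.19) did not pass, nor did Aif1 (0.16 ± 0.24) and Apoe (0.18 ± 0.19). P2ry12 and Tmem119 passed with the replicate block (edgeR, BH-adjusted p = 0.00774 and 0.00723), with the oligodendrocyte covariate (0.0129 and 0.0357) and without saline library 1 (0.0338 and 0.041). P2ry12 also passed with no filter (0.0205) and without MPTP library 3 (0.0403), and Tmem119 with voom (0.0466). Of 75 ribosomal protein genes 6 rose (6 adjusted over the list alone, median 0.29, adjusted p = 0.289 with an estimated correlation), such as Rpl35 (0.71 ± 0.16), Rpl32 (0.68 ± 0.13) and Rpl10a (0.55 ± 0.12).

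The lowest genes were Synpo2 (-1.77 ± 0.45), Cd209f (-1.59 ± 0.40), Nwd2 (-1.48 ± 0.18), Fv1 (-1.46 ± 0.33), the phospholipase Pla2g2d (-1.35 ± 0.39) and Th, from 196 ± 25.1 to 80.5 ± 20.2 CPM (-1.28 ± 0.18). Of 21 dopaminergic markers 14 fell in these microglial libraries (18 adjusted over the list alone, median -0.97, adjusted p = 0.0735 with an estimated correlation). Of 13 pan-neuronal markers 9 fell (11 adjusted over the list alone, median -0.61, adjusted p = 0.156 with an estimated correlation), as did 10 of 14 synaptic vesicle genes (14 adjusted over the list alone, median -0.48, adjusted p = 0.225 with an estimated correlation). The length score was 0.98 ± 0.21 (SD, n = 3) in saline and 0.695 ± 0.17 (n = 3) after MPTP. In all, 1562 of 17257 genes passed, 872 higher and 690 lower (edgeR, BH), with 55.8% of the calls higher under TMM and 77.2% under plain library sizes. Same-numbered libraries were correlated (r across genes 0.211 to 0.845), and 4241 genes passed with the replicate block, 722 without the saline library that holds Xist and 580 without MPTP library 2.

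In microglia of the striatum, cell division genes were the highest after MPTP. Ccnb1, the mitotic cyclin (chromosome 13, 100778650 to 100786570), rose from 1.30 ± 0.66 CPM (SD, n = 4) to 134 ± 53.1 (n = 3), a log2 fold change of 6.72 ± 0.46 (SE; edgeR, BH-adjusted p = 5.17e-08). Birc5, a chromosomal passenger protein, rose by 6.68 ± 0.37, the ubiquitin-conjugating enzyme Ube2c by 6.37 ± 0.31, the cyclin Ccnb2 by 6.31 ± 0.33, the replication factor Pclaf by 6.17 ± 0.46 and the kinase Aurkb by 6.13 ± 0.35. All 20 proliferation genes rose (20 adjusted over the list alone, median 4.49, adjusted p = 0.297 with an estimated correlation), with Bub1 at 6.03 ± 0.32 and Top2a at 5.49 ± 0.29. Aif1 (0.83 ± 0.22), Cd68 (0.86 ± 0.17) and Tnf (1.61 ± 0.56) rose and Apoe fell by 0.62 (SE 0.18). Il1b (0.91 ± 0.41), Cx3cr1 (-0.17 ± 0.18), P2ry12 (-0.27 ± 0.30) and Tmem119 (-0.27 ± 0.17) did not pass. With the oligodendrocyte and the length covariate Aif1 turned to -0.13 and -0.40 (edgeR, BH-adjusted p = 0.836 and 0.165), and Cd68 (0.515 and 0.728) and Apoe (0.531 and 0.74) did not pass. Aif1 did not pass without MPTP library 1 (0.0819), nor Tnf without MPTP library 1 or 3 or saline library 1, 2 or 4 (0.0936 to 0.164), with plain library sizes (0.0571), voom (0.0801), the length covariate (0.192), the Xist covariate (0.113) or without Xist libraries (0.23). Il1b passed with the replicate block (0.0432), voom (0.0434) and the 2 groups alone (0.0383), P2ry12 with the oligodendrocyte covariate (0.0267) and Tmem119 with the 2 groups alone (0.0461).

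Nuclear genes of the respiratory chain were higher. Of 35 genes of complexes II to V 30 rose (33 adjusted over the list alone, median 0.63, adjusted p = 0.416 with an estimated correlation), with Uqcr10 at 0.87 ± 0.13, Cox6b1 at 0.80 ± 0.12 and Uqcr11 at 0.68 ± 0.11. Of 37 genes of complex I 28 rose (30 adjusted over the list alone, median 0.54, adjusted p = 0.475 with an estimated correlation), with Ndufa1 at 0.995 ± 0.13, Ndufb11 at 0.93 ± 0.13 and Ndufa3 at 0.88 ± 0.13. The length score fell from 0.73 ± 0.09 (SD, n = 4) to 0.10 ± 0.20 (n = 3) in the same libraries, and with it as a covariate the complex I list was not higher (camera, BH-adjusted p = 0.685 in the other direction). The score did not overlap between treatments (0.607 to 0.803 in saline, -0.05 to 0.322 after MPTP), and list members can enter it. This covariate therefore cannot tell a length bias from a rise of the list.

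Neuronal genes were lower in these microglial libraries. All 14 synaptic vesicle genes fell (14 adjusted over the list alone, median -1.03, adjusted p = 0.297 with an estimated correlation), among them Syn1 (-1.32 ± 0.14) and Syn2 (-1.05 ± 0.13). All 13 pan-neuronal markers fell (13 adjusted over the list alone, median -1.03, adjusted p = 0.297 with an estimated correlation), among them Stmn2 (-1.53 ± 0.13), Nefm (-1.24 ± 0.14) and Snap25 (-1.03 ± 0.13). The lowest genes were the brain serine protease Prss12 (-3.63 ± 0.39), the nuclear receptor Nr4a2 (-3.61 ± 0.42), the glutamate transporter Slc17a7 (-2.98 ± 0.52), Cplx3 (-2.76 ± 0.40), Pla2g2d (-2.71 ± 0.45) and the neuropeptide gene Cck (-2.70 ± 0.36). In all, 6115 of 17257 genes passed, 3128 higher and 2987 lower (edgeR, BH), and 7858 with the replicate block. The share of higher calls was 51.2% under TMM, 43% under RLE and 40.4% under plain library sizes, and 2398 genes passed with the length score and 1792 with the oligodendrocyte list as a covariate.

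In microglia the region by treatment test gave larger effects in the substantia nigra for cytokine and interferon genes and larger effects in the striatum for cell division genes. Ccl3 differed by 4.56 ± 0.47 (SE; edgeR, BH-adjusted p = 0.000573), Ccl4 by 4.58 ± 0.52, Gfap by -3.16 ± 0.35, Asb4 by -3.15 ± 0.35 and the predicted gene Gm43305 by -2.59 ± 0.27. Gfap, an astrocyte gene, lay at 15.5 ± 2.49 CPM (SD, n = 4) in saline and 262 ± 32.0 (n = 3) in MPTP microglial libraries of the striatum, against 748 and 19650 in those of astrocytes. Of 16 cytokine genes 5 had a larger effect in the substantia nigra (13 adjusted over the list alone, median 2.22), as had 9 of 21 interferon genes (17 adjusted over the list alone, median 1.38). For both, adjusted p = 0.161 with an estimated correlation. Of 20 proliferation genes 9 had a smaller effect there (11 adjusted over the list alone, median -1.62), as had 6 of 37 complex I genes (30 adjusted over the list alone, median -0.65) and 6 of 35 genes of complexes II to V (28 adjusted over the list alone, median -0.66). For these 3 lists, adjusted p = 0.297 with an estimated correlation. The length score fell from 0.73 to 0.10 in striatal microglia, and with it as a covariate the 2 respiratory chain lists had medians of -0.33 and -0.325 in this test and -0.097 and -0.007 in the striatum alone.

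In all, 468 genes passed this test in microglia, 124 positive and 344 negative (edgeR, BH), and 1864 with the replicate block. The share of positive calls was 26.5% under TMM, 39.3% under RLE and 52.9% under plain library sizes, with the median of all genes at -0.05 under TMM and 0.12 under plain sizes. Without the saline libraries that hold Xist 141 passed, and 231 without MPTP library 1 of the striatum.

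**Figure D3:**
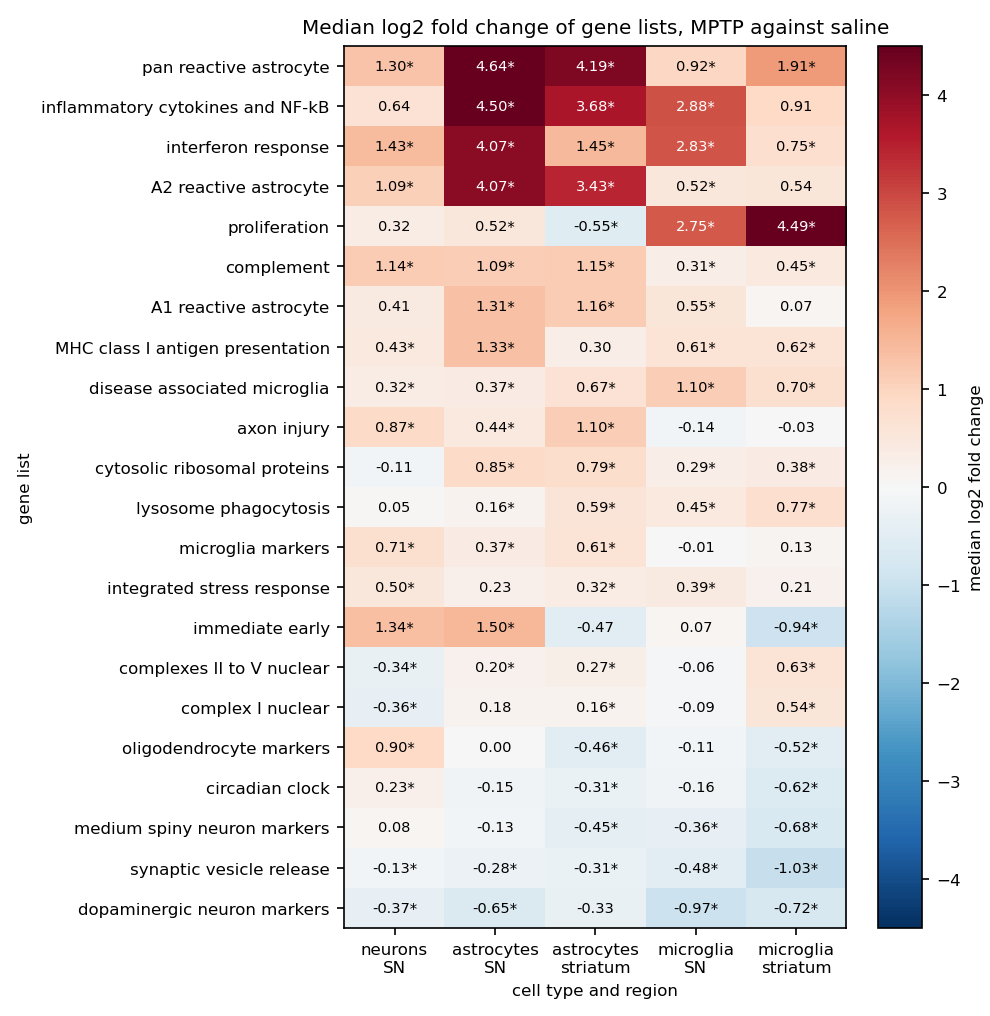
Median log2 fold change, MPTP against saline (colour and number), of the 22 gene lists past a camera adjusted p of 0.05 in at least 3 of the 5 comparisons (y axis), by cell type and region (x axis; SN, substantia nigra), with an asterisk where the list passed at the preset correlation. Proliferation genes reach 4.49 in microglia of the striatum and interferon genes 4.07 in astrocytes of the substantia nigra (camera, BH-adjusted p = 0.297 and 0.0901 with an estimated correlation, which 4 of 166 list calls in all comparisons pass).

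Within the substantia nigra the MPTP effect was tested for a difference among the 3 cell types. Of 18021 genes 981 passed (edgeR F test, BH), with the largest change in astrocytes for 528, in microglia for 274 and in neurons for 179. Synpo led, with F = 167 (edgeR, BH-adjusted p = 3.17e-09) and log2 fold changes of 4.26 ± 0.21 (SE) in astrocytes, 0.05 ± 0.15 in neurons and -0.19 ± 0.19 in microglia. It was followed by the phosphatase Dusp5 (F = 90.5), S1pr3 (F = 83.7), Junb (F = 74.4) and Gfra1 (F = 69.1), with changes in astrocytes of 6.91 ± 0.45, 5.59 ± 0.37, 4.48 ± 0.28 and 2.55 ± 0.21. Of 20 proliferation genes 12 passed, with medians of 2.85 in microglia, 0.67 in neurons and 0.45 in astrocytes. Of 21 interferon genes 11 passed, with medians of 3.99 in astrocytes, 2.93 in microglia and 1.72 in neurons. Without MPTP library 1 of astrocytes 581 genes passed, and 3879 with the replicate block, 1776 with DESeq2 and 8734 with limma voom.

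In saline astrocytes the regions differed by neuronal and cell division genes. Dao, D-amino acid oxidase (chromosome 5, 114003703 to 114025682), lay at 57.4 ± 0.53 CPM (SD, n = 3) in the substantia nigra and 0.19 ± 0.10 (n = 3) in the striatum, a log2 fold change of 8.21 ± 0.49 (SE; edgeR, BH-adjusted p = 2.13e-08). The homeobox genes Irx2 (7.46 ± 0.38) and Irx1 (7.31 ± 0.35), the glutamate transporter Slc17a6 (6.36 ± 0.45), Ret (6.32 ± 0.39) and Slc6a3 (9.06 ± 0.59) were higher in the substantia nigra. Prss56, with 1 count in the substantia nigra, was lower there by a ratio of 3000 (95% interval 539 to 119000), and Igfbpl1, also with 1 count, by 2240 (402 to 88500). Crym (-10.57 ± 0.68), Pclaf (-8.29 ± 0.50), Lrrc10b (-7.06 ± 0.40) and the thrombospondin Thbs4 (-7.03 ± 0.49) were also lower.

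Of 20 proliferation genes 19 were lower in astrocytes of the substantia nigra (19 adjusted over the list alone, median -3.96, adjusted p = 0.204 with an estimated correlation), among them Cdk1 (-6.93 ± 0.32), Ccna2 (-6.07 ± 0.31) and Mcm5 (-4.02 ± 0.24). Of 14 immediate early genes 11 were lower (11 adjusted over the list alone, median -1.96, adjusted p = 0.358 with an estimated correlation), with Npas4 at -3.14 ± 0.25, Egr4 at -6.04 ± 0.55 and Egr2 at -5.72 ± 0.55. Markers of neighbouring cells followed the region. Of 20 dopaminergic markers 18 were higher and 1 lower in the substantia nigra (18 and 1 adjusted over the list alone, median 4.11). Among the higher ones Aldh1a1 (2.80 ± 0.17) was not among the genes enriched in neurons. It lay at 1933 ± 340 CPM (SD, n = 3) in these astrocytes and 278 ± 54.9 (n = 3) in those of the striatum. Of 13 medium spiny neuron markers 12 were lower (12 adjusted over the list alone, median -4.56), with Drd1 at -6.27 ± 0.29, Pde10a at -4.85 ± 0.25 and Rgs9 at -4.56 ± 0.21. For both, adjusted p = 0.204 with an estimated correlation. Of 14 oligodendrocyte markers 13 were higher (13 adjusted over the list alone, median 0.95, adjusted p = 0.358 with an estimated correlation), among them Gjc3 (2.33 ± 0.18) and Aspa (1.69 ± 0.16). Of 6 choroid plexus and ependymal markers 3 were lower (3 adjusted over the list alone, median -0.79, adjusted p = 0.358 with an estimated correlation), with a mean log2 CPM of 3.09 against 4.64 in the striatum.

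Gfap (2.37 ± 0.18), Aqp4 (2.22 ± 0.18) and Serpina3n (0.97 ± 0.22) were higher in astrocytes of the substantia nigra, Slc1a2 (-0.99 ± 0.14), Slc1a3 (-0.69 ± 0.12) and Vim (-1.36 ± 0.25) were lower, and Lcn2 did not pass (-0.40 ± 1.23). With the oligodendrocyte covariate Slc1a2, Slc1a3 and Vim did not pass (edgeR, BH-adjusted p = 0.478, 0.671 and 0.224), nor did Slc1a3 and Vim without Xist libraries (0.0611 and 0.0816). In all, 5723 of 16661 genes passed, 2608 higher and 3115 lower (edgeR, BH), and 7132 with the replicate block. The share of higher calls was 45.6% under TMM and 30% under plain library sizes, with the median of all genes at -0.03 and -0.19, and 2424 genes passed without the libraries that hold Xist and 1349 with the oligodendrocyte covariate.

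In saline microglia the regions differed most by genes of neurons. Slc6a3 (chromosome 13, 73536747 to 73578672) lay at 325 ± 59.3 CPM (SD, n = 3) in the substantia nigra and 0.11 ± 0.21 (n = 4) in the striatum, a log2 fold change of 11.46 ± 0.45 (SE; edgeR, BH-adjusted p = 8.8e-11). Chrna6, with 3 counts in the striatum, was higher by a ratio of 1160 (95% interval 397 to 5640). Chrnb3 (7.14 ± 0.27), the neuropeptide gene Adcyap1 (7.03 ± 0.39), Sncg (6.45 ± 0.31) and Ddc (6.42 ± 0.21) were higher in the substantia nigra. Sh3rf2 (-7.84 ± 0.39), Ankrd63 (-7.71 ± 0.42), the adenosine receptor Adora2a (-7.36 ± 0.40), Lrrc10b (-6.78 ± 0.23) and Dnah6 (-6.75 ± 0.34) were lower.

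Of 21 dopaminergic markers 20 were higher and 1 lower in microglial libraries of the substantia nigra (20 and 1 adjusted over the list alone, median 6.42, adjusted p = 0.0516 with an estimated correlation), with Slc18a2 at 5.13 ± 0.17. All 13 medium spiny neuron markers were lower (13 adjusted over the list alone, median -3.64, adjusted p = 0.0525 with an estimated correlation), with Bcl11b at -3.82 ± 0.15 and Pde10a at -3.64 ± 0.17. Of 13 pan-neuronal markers 11 were higher and 1 lower (11 and 1 adjusted over the list alone, median 1.82, adjusted p = 0.32 with an estimated correlation), with Slc17a6 at 6.27 ± 0.20, Nefm at 3.14 ± 0.13 and Nefl at 2.59 ± 0.13, and of 14 synaptic vesicle genes 12 were higher and 1 lower (12 and 1 adjusted over the list alone, median 1.84, adjusted p = 0.357 with an estimated correlation), with Cplx1 at 2.42 ± 0.13, Napb at 2.15 ± 0.12 and Nsf at 2.15 ± 0.12.

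Microglial genes were lower in the substantia nigra. Of 22 microglial markers 20 were lower (21 adjusted over the list alone, median -0.86, adjusted p = 0.513 with an estimated correlation), with Tmem119 at -0.89 ± 0.18, Cx3cr1 at -0.86 ± 0.19 and Aif1 at -0.85 ± 0.23, and Cd68 (-0.94 ± 0.18) and Apoe (-0.50 ± 0.18) were lower too. P2ry12 (-0.75 ± 0.30), Il1b (-0.06 ± 0.43) and Tnf (0.74 ± 0.59) did not pass. With the oligodendrocyte covariate none of these passed (edgeR, BH), and some turned sign. Apoe did not pass with plain library sizes (0.0721), without Xist libraries (0.0842) or without library 1 or 2 of the substantia nigra or 3 or 4 of the striatum (0.0793 to 0.105). P2ry12 passed with no filter (0.000317), DESeq2 (0.0256) and voom (0.0461), and without library 2 of the substantia nigra P2ry12 (0.0292) and Il1b (0.0432, at -1.03) passed. Of 75 ribosomal protein genes 57 were lower (61 adjusted over the list alone, median -0.55, adjusted p = 0.513 with an estimated correlation), with Rpl31 at -0.70 ± 0.12. In all, 7565 of 17257 genes passed, 4134 higher and 3431 lower (edgeR, BH), and 4629 with the oligodendrocyte covariate.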

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

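The tests of glial markers in neurons and of Xist and the counts of other splits were chosen after the results they address were seen. For the ribosomal protein genes the result was known, and only the excess over matched genes had not been seen when its test was written.

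Glial and vascular markers were higher in the MPTP libraries of dopaminergic neurons, with a median over 5 list medians of 0.90. Those lists lie at 0.521 and 1.265 within the clusters of high and low length score. Each cluster holds saline and MPTP libraries, so the clusters could hardly have given the rise. With so few libraries in each, these medians are no separate test of it. A larger share of RNA from the surrounding tissue may account for the rise: 1030 genes outside the lists that are higher in unselected tissue had a median 0.709 above that of all genes, with 89.2% positive. The list medians ran from 0.711 to 1.18, a difference of 2.58 standard errors against a 95% point of 2.73 for the highest and lowest of 5; this criterion replaced one of 2 standard errors after the value was seen, and the earlier one would have argued against tissue RNA. More glial and vascular RNA in the tissue itself, at 0.228 in single unselected libraries, cannot be told apart from a response of the neurons because there is 1 library per treatment.

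Xist exceeded 1 CPM in 9 of 19 saline libraries, at 5.9 to 97.3 CPM, and reached at most 0.567 CPM in 19 MPTP libraries. Saline libraries made from animals of both sexes may account for it: 4 Y-linked genes were lower by a mean log2 difference of -0.621 in saline libraries with Xist than without it, and lower in 4 of 4 groups. An effect of MPTP on Xist cannot be told apart, since the MPTP libraries differed from saline libraries without Xist by 0.093 in those Y-linked genes, with a lower 95% bound of -0.32 over 4 groups. This test replaced a count of the 10 saline libraries without Xist, and its bound was made stricter, both after values had been seen.

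Cytosolic ribosomal protein genes were higher in the MPTP libraries of astrocytes, whose length scores were lower. Genes matched on length and level argue against length bias as the whole source: the ribosomal protein genes exceeded them by a median of 0.735 (95% interval 0.687 to 0.793) in the substantia nigra and 0.609 (0.546 to 0.701) in the striatum. The intervals cover the choice of genes, not the spread between animals. Without the saline libraries that hold Xist the medians of the cytosolic ribosomal proteins list were 0.912 and 0.899, so the rise was also present without them. This leaves a single saline library per region and so no replicate check. A response of astrocytes to MPTP may account for the rise and stays a hypothesis, since of RNA from other cells only that of oligodendrocytes was covered, with medians of 0.844 and 0.724 under their marker covariate, and its adjusted p with an estimated correlation was 0.117 and 0.168 (camera, BH).

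In 155 tests for a library far from the others of its group 11 stood out, where chance gives about 1 in 20. In MPTP libraries of neurons the gap over the range was 0.728 for Cldn11 (library 2, high), 0.82 for Cldn5 (library 1, low) and 0.87 for the dopaminergic markers (library 3, high). That library lay at 9.149 in these markers, within the 9.058 to 9.409 of all saline libraries. It lay below saline libraries 2 and 3 (9.409 and 9.391), which share its cluster of low length score. The median without MPTP library 3 was -0.447. In saline microglia of the striatum it was 0.874 for Ccnb2 (library 1, high), 0.833 for Rpl31 (library 2, low), 0.901 for Stmn2, 1 for Slc6a3 and 0.832 for Slc18a2 (library 3, high), and 0.869 for Syn2, 0.847 for Nsf and 0.865 for the pan-neuronal markers (library 4, low).

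The MPTP effect differed between regions in astrocytes for 202 genes, for Synpo (2.68), Gfap (-2.88), A2m (-2.18), Gfra1 (2.75) and Cmpk2 (4.08), and by list medians of 2.12 for interferon, 1.82 for immediate early, 1.07 for proliferation, 1.18 for MHC class I and 1.16 for cytokine genes. With an estimated correlation the camera BH-adjusted p of these lists ran from 0.136 to 0.493. In microglia it differed for 468 genes, for Ccl3 (4.56), Gm43305 (-2.59), Asb4 (-3.15), Gfap (-3.16) and Ccl4 (4.58), and by list medians of 1.38 for interferon, 2.22 for cytokine, -0.65 for complex I, -0.66 for complexes II to V and -1.62 for proliferation genes. None of these lists passed with an estimated correlation, and the respiratory chain medians were smaller in size with the length score as a covariate. Among cell types of the substantia nigra the MPTP effect differed for 981 genes, with F at 167 for Synpo, 90.5 for Dusp5, 83.7 for S1pr3, 74.4 for Junb and 69.1 for Gfra1.

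Both unselected saline libraries hold Xist, at 17.2 and 71.4 CPM in the substantia nigra and striatum, against 0 and 0.447 in the MPTP libraries. Their length scores were 0.644 and 0.537, against -0.006 and -0.244 after MPTP, so the ratios below compare libraries that also differ in these. In the unselected libraries, 1 per treatment and region, 13 lists in the substantia nigra and 12 in the striatum lay at percentile 99.94 of random lists or higher by their median log2 ratio of MPTP to saline. In the substantia nigra these were interferon (2.75), cytokine (2.42), shared reactive astrocyte (1.84), MHC class I (1.61), complement (1.59), immediate early (1.04), A1 (0.96), disease-associated microglia (0.86), integrated stress response (0.69), lysosome (0.58), microglial marker (0.48), ribosomal protein (0.32) and complex II to V (0.29) genes. In the striatum they were shared reactive astrocyte (2.31), complement (1.45), A2 (1.31), sex-linked (1.10), disease-associated microglia (0.98), lysosome (0.92), microglial marker (0.85), proliferation (0.76), A1 (0.75), ribosomal protein (0.47), complex II to V (0.39) and complex I (0.38) genes.

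Other splits of the same samples were refitted. For neurons 4 of 100 splits gave as many genes as the 322 of the real one, a share under 0.05 in a draw from 126, and the highest other gave 6127. That split follows the clusters of length score and so points to a structure of the samples, within which 941 and 103 genes passed, and 3698 with the clusters as a batch term. The 10 splits that part 4 same-numbered pairs gave at most 0 genes but are too few for a share under 0.05, so these counts do not firmly exclude chance. For microglia of the striatum 1 of 35 splits, the real one, gave 6115 (highest other 1299). For the regions of saline microglia 1 of 35 gave 7565 (highest other 2418). Only 7 others in each part as many same-numbered pairs, too few for a share under 0.05 (highest 1299 and 1559). In the striatum MPTP libraries 2 and 3 correlated best with saline libraries 1 and 4, against their numbers. The r of pairs between regions was -0.502, 0.484 and 0.355. Chance is not firmly excluded in either.

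Fewer than 5 of 100 splits gave as many genes for the region test in astrocytes (3 of 100 splits, 202 genes, highest other 1169), the region test in microglia (4 of 100, 468 genes, highest other 2808) and the cell type test (2 of 100, 981 genes, highest other 3306). These splits are a draw of 100 from more and were not matched on same-numbered pairs, so the shares could lie above 0.05 and chance is not firmly excluded. Labels swapped within a region or cell type can also turn an MPTP effect shared by all into a difference. The counts of other splits are therefore no clean reference for such a difference. The highest others are several times the real counts. In the region tests they swap most treatment labels of 1 region and keep those of the other, so the MPTP effect itself enters these counts. In the cell type test the highest other moves labels of neuron and microglial libraries. For genes enriched in astrocytes (1 of 90 splits, 2607 genes, highest other 216) and microglia (1 of 90, 1972 genes, highest other 158) no other split gave as many. Splits that mix the captured cell types are bound to give few such genes, so these counts do not firmly exclude chance. For genes enriched in neurons 5 of 90 splits gave as many as 1405, with 2210 as the highest other. Each of the 4 others put all 3 astrocyte libraries in the group tested and so counts genes of astrocytes, which leaves this count without a bearing on chance. Splits were too few for astrocytes of the substantia nigra (1 of 10, 2326 genes, highest other 0), astrocytes of the striatum (1 of 10, 2977, highest other 1), microglia of the substantia nigra (1 of 10, 1562, highest other 4) and the regions of saline astrocytes (1 of 10, 5723, highest other 0).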

How the results depend on the processing

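Alternatives with the length score, Xist, the length clusters, their batch term and the numbers in file headers were chosen after seeing the data. With scaling by RLE or plain library sizes and with a mean of at least 50 counts no count of genes moved over 1.5 times. The cause was not tested for the changes below, except that leaving out libraries or fitting fewer leaves fewer samples. Without the libraries that hold Xist, saline astrocytes keep 1 library per region, which is assumed to vary like the other groups. Depth limits genes with few counts, given above by bounds.

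In neurons (322) the count was 1234 with DESeq2, 9896 with limma voom, 140 with the threshold on fold change, 1 with the oligodendrocyte covariate, 3424 with the replicate block, 3801 with the block by header numbers, 1068 with all cell types in 1 fit, 1865 with the length covariate, 3698 with the batch term, and 941 and 103 within the clusters of low and high length score. In astrocytes of the substantia nigra (2326) it was 3731 with voom, 927 with the fold threshold, 1268 with the length covariate and 1114 without Xist libraries. In those of the striatum (2977) it was 5901 with voom, 1021 with the fold threshold, 885 with the oligodendrocyte covariate and 877 without Xist libraries. In microglia of the substantia nigra (1562) it was 2366 with DESeq2, 603 with the fold threshold, 4241 with the block, 697 with the 2 groups alone, 753 with all cell types in 1 fit, 2473 with the length covariate and 722 without Xist libraries. In those of the striatum (6115) it was 2061 with the fold threshold, 1792 with the oligodendrocyte and 2398 with the length covariate.

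For the region test in astrocytes (202) the count was 616 with no filter, 468 with DESeq2, 347 with voom, 102 with the oligodendrocyte covariate and 13 without Xist libraries. In microglia (468) it was 1096, 989, 1558, 248 and 141 under the same settings and 1864 with the block. For regions in saline astrocytes (5723) it was 3140 with the fold threshold, 1349 with the oligodendrocyte covariate and 2424 without Xist libraries, and in saline microglia (7565) 3272 with the fold threshold and 4629 with the oligodendrocyte covariate. The cell type test (981) gave 3879 with the block, 1776 with DESeq2 and 8734 with voom. Of 166 list calls 4 held with an estimated correlation, 157 with the block and 119 with fry, which tests each list against no change and called 158 in all. Of the 103 calls in treatment comparisons 79 held with any 1 library left out, tested after the results were seen.

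Leaving out 1 library gave 27 to 918 genes in neurons. It gave 31, 30, 27 and 918 without saline libraries 1 to 4, and 147, 35 and 41 without MPTP libraries 3 to 5. Astrocytes of the substantia nigra ranged from 1217 to 2121, with 1217 and 1267 without MPTP libraries 1 and 2. Those of the striatum ranged from 1544 to 3739, with 1712 without saline library 2 and 1544 and 1562 without MPTP libraries 1 and 2. Microglia of the substantia nigra ranged from 580 to 1422, with 1005 and 956 without saline libraries 1 and 2 and 1034 and 580 without MPTP libraries 1 and 2, and those of the striatum from 4220 to 6394.

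The region test in astrocytes ranged from 96 to 240. In the substantia nigra it gave 130 without saline library 1 and 96 and 106 without MPTP libraries 1 and 2, and in the striatum 116 and 106 without saline libraries 1 and 2 and 123 without MPTP library 1. In microglia it ranged from 231 to 769. In the substantia nigra it gave 296 without saline library 3 and 284 without MPTP library 1, and in the striatum 276 and 295 without saline libraries 2 and 3 and 231, 254 and 769 without MPTP libraries 1, 2 and 3. Regions ranged from 4562 to 5838 in saline astrocytes and from 6188 to 7253 in saline microglia. The cell type test ranged from 581 to 1342, with 581 and 633 without astrocyte MPTP libraries 1 and 2. Enriched genes ranged from 1319 to 1501 for neurons, 2481 to 2637 for astrocytes and 1816 to 2081 for microglia.

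Some log2 fold changes changed sign, none of them past the threshold afterwards. Cdkn1a in neurons was -0.12 with voom. Aqp4 in astrocytes of the substantia nigra was -0.001 without saline library 1 (0.227 without saline library 3), -0.15 with the Xist covariate and -0.21 without Xist libraries. Aif1 in microglia of the substantia nigra was -0.04 with voom, -0.084 with the oligodendrocyte and -0.39 with the length covariate, -0.05 without saline library 1 and -0.14 without MPTP library 2. In the striatum Aif1, which had passed, was -0.13 and Il1b -0.076 with the oligodendrocyte covariate, and -0.40 and -0.13 with the length covariate. Between regions of saline astrocytes Lcn2 was 2.39 with voom, 0.75 with the oligodendrocyte covariate, 0.11 without library 3 of the substantia nigra and 2.58 without library 1 of the striatum, with -1.24 (-1.235) as the lowest when 1 library was left out. Between regions of saline microglia, with the oligodendrocyte covariate, Aif1, which had passed, was 0.16, P2ry12 0.69, Il1b 0.96 and Tnf -0.54. Il1b there was also 0.004 with plain library sizes, 0.31 and 0.20 without libraries 1 and 3 of the substantia nigra, 0.12 without library 4 of the striatum, 0.26 with the length covariate and 0.009 with the Xist covariate, and -1.03 (-1.026) at the lowest when 1 library was left out.

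Lists that turned direction had these camera BH-adjusted p, with the range over alternatives in brackets. With the oligodendrocyte covariate in neurons they were 0.822 for precursor markers (0.000661 to 0.822), 0.822 for heat shock (0.00419 to 0.822), 0.669 for glucocorticoid response (0.000206 to 0.669), 0.988 for complexes II to V (1.73e-08 to 0.988), 0.469 for mitochondrially encoded genes (0.000126 to 0.654) and 0.266 for synaptic vesicle genes (0.0506 to 0.531). The mitochondrially encoded list gave 0.654 in the cluster of high length score. With the length covariate, camera BH-adjusted p was 0.326 for complexes II to V in astrocytes of the substantia nigra (0.000612 to 0.817) and 0.363 for complex I in those of the striatum (1.96e-06 to 0.721). In microglia of the striatum it was 0.747 for precursor markers (0.00763 to 0.747), 0.37 for MHC class I (0.00117 to 0.614), 0.685 for complex I (9.11e-10 to 0.685) and 0.37 for ribosomal protein genes (5.86e-08 to 0.497), and with the oligodendrocyte covariate 0.359 for precursor markers and 0.614 for MHC class I. That covariate gave 0.935 for precursor markers in the region test of microglia (0.00367 to 0.935), and between regions of saline microglia 0.777 for MHC class I (0.0174 to 0.777) and 0.502 for the unfolded protein response (0.00737 to 0.652).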

Other observations

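Of 14679 genes measured in every cell type, 13 were higher in the libraries of all 5 treatment comparisons and 1 was lower (edgeR, BH). Glial and vascular markers were also higher in the MPTP libraries of neurons, by 0.90, and Gfap in those of striatal microglia lay at 262 CPM against 19650 in astrocytes. Gbp2, an interferon-induced GTPase, rose by 3.12 in neurons, 5.79 and 2.79 in astrocytes of the substantia nigra and striatum, and 2.31 and 1.78 in microglia of these regions, on the log2 scale. In the same order Cd68 rose by 2.99, 3.11, 1.75, 1.248 and 0.86, and Mt1, a metallothionein, by 1.62, 1.16, 1.01, 1.18 and 1.18. Rsad2, Gfap, Wwtr1, Adam15, Arpc1b, H2-Q4, Clic4, Maff, Ezr and Olfr920 also rose in all 5, and Homer2, a scaffold protein of synapses, fell by 1.19 (log2) in neurons. In all 4 glial comparisons 131 of 15718 genes rose and 41 fell. Astrocytes of the 2 regions shared 923 genes that rose, where 152 are expected if the calls were independent, and microglia shared 680, where 158 are expected. The regions of a cell type share 1 fit, and same-numbered saline astrocyte libraries were correlated between regions (r 0.425 to 0.653). The calls were therefore not independent, and overlap above these values does not by itself show a shared response. Neurons shared 54 higher and 23 lower genes with astrocytes of the substantia nigra, where 11.4 and 9.77 are expected (Fisher's exact test, BH-adjusted p = 1.08e-23 and 0.000138), and 25 and 34 with microglia there, where 5.17 and 8.45 are expected (5.75e-11 and 4.23e-12). With astrocytes of the striatum they shared 42 and 17, where 13.2 and 14.4 are expected (BH-adjusted p = 4.23e-12 and 0.27), and with microglia of the striatum 28 and 53, where 23.1 and 35.9 are expected (0.164 and 0.00173). Fisher's exact test treats genes as independent, which they are not, so these p-values do not measure the spread between samples.

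Some lists not described above also moved. In microglia of the striatum 10 of 14 clock genes fell and 1 rose (10 and 1 adjusted over the list alone, median -0.62), among them Nr1d1 (-1.51 ± 0.15), a nuclear receptor of the clock, Dbp (-0.82 ± 0.19) and Arntl (-0.75 ± 0.13). The camera BH-adjusted p was 0.00195, and adjusted p = 0.297 with an estimated correlation. In the same libraries the mean log2 CPM of pan-neuronal markers went from 6.25 to 5.06, that of oligodendrocyte markers from 4.94 to 4.33 and the length score from 0.73 to 0.10. Of 19 cholesterol synthesis genes 15 were higher in saline microglia of the substantia nigra than of the striatum (15 adjusted over the list alone, median 0.76), among them Sqle (1.51 ± 0.13). The camera BH-adjusted p was 4.8e-06, and adjusted p = 0.32 with an estimated correlation. Mean log2 CPM there and in the striatum was 8.06 and 6.25 for pan-neuronal, 5.67 and 4.94 for oligodendrocyte and 9.84 and 10.68 for microglial markers. In neurons no gene of complex I (0 of 37) or complexes II to V (0 of 35) passed in edgeR, with medians of -0.36 and -0.34 (camera BH-adjusted p = 0.000235 and 0.000217, and adjusted p = 0.575 for both with an estimated correlation). Of 16 interferon genes 1 rose in neurons (11 adjusted over the list alone, median 1.43, adjusted p = 0.348 with an estimated correlation).

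In the unselected substantia nigra, with 1 library per treatment, the log2 ratio of MPTP to saline was -1.07 for Th, -1.31 for Slc18a2, 2.70 for Cdkn1a, 1.96 for Gfap and 2.91 for Ifit3. The dopaminergic markers had a median of -0.95 (-0.945), at percentile 0 of random lists. In the striatum the ratio was 5.03 for Gfap, 3.34 for Vim and 2.23 for Cdkn1a, and the immediate early list had a median of -0.65, at percentile 0.01. There Th (0.61) and Ddc (0.79) were positive and Slc18a2 (-0.53) negative. Lcn2, which rose in astrocytes of both regions, had ratios of -0.20 in the substantia nigra and -0.46 in the striatum. It lay at 26.4 CPM in the unselected saline substantia nigra, against 0.37 ± 0.31 (SD, n = 3) in saline astrocytes there. In both regions the saline library holds Xist and the MPTP library does not exceed 0.447 CPM of it.

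The files of neurons and microglia and those of astrocytes and unselected tissue may rest on different annotations, a limit of the enriched genes and the cell type test for which the replicate block gave 3879 genes. With at least 1 CPM in every other library, 1 gene (Hgs) was at 0 in all 22 libraries of neurons and microglia, and 1 (Gm17383) was at 0 in all 16 of the others. With a mean of 1 CPM, a criterion chosen after that result was seen, the counts were 3 and 7, of which 1 was among the genes enriched in astrocytes and 0 passed the cell type test.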
